A study of Homo sapiens with 6 samples.

How the data were processed

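RNA was measured in 6 samples of HK-2, an immortalised line of human kidney proximal tubule cells, with 1 one-colour Agilent array per sample. Of these, 3 samples were kept in 5.5 mM glucose and 3 in 25 mM glucose, and RNA was taken after 72 h. Per the labels' protocols, cells were cultured for 12 h before the medium was changed, total RNA was extracted with TRIzol, and the amplified RNA was labelled with Cy3. The series' design text speaks of independent experiments from different batches, but it does not say that a replicate number marks a batch. No sample with an osmotic control sugar was analysed here.

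Per the file headers, the authors read the scans with Agilent Feature Extraction 11.0.1.1, protocol GE1_1100_Jul11, on a design whose grid refers to build hg19 (GRCh37). The deposited processed signal is an intensity: the Cy3 brightness of a spot after background subtraction and detrending within the array, with no scaling between arrays. The deposited median spot signal and median local background are also intensities, before any subtraction. The authors' value table of the whole series holds the same intensities as the processed signal, with a largest difference of 0, so its scale is linear and it carries no further centring. Its column medians were 72.9, 78.3 and 67.6 for normal glucose replicates 1 to 3 and 75.3, 77.9 and 83.7 for high glucose replicates 1 to 3.

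Each array held 44495 spots, of which 43118 were gene spots for 34127 probes, and 999 probes were printed 10 times. Spots flagged as non-uniform or as population outliers were left out (330 to 535 gene spots per array), and no spot was saturated. The processed signal was turned to log2, the 75th percentile of each array (633.7 to 749.2 on the linear scale) was subtracted, and spots of 1 probe were averaged. Between 65.2% and 69.2% of the probes were well above background on an array. The files pair probes with accessions and hold no gene symbols. Accessions were matched without versions to a RefSeq table (assembly GRCh38.p14), which named 25771 probes (75.5%) for 19740 genes and left 8356 unnamed. Because the builds differ, no coordinate of that table is printed, and the span of a gene, from its first to its last base, served only as a rounded property of the gene.

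A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 22131 probes. A gene was represented by its tested probe with the highest mean over all 6 arrays, and a probe without a name stood for itself. Of 3318 genes with several tested probes, 849 had 2 or more called probes, and in 44 of these the probes were called in opposite directions. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), and p-values were adjusted by the method of Benjamini and Hochberg over the features tested, with a threshold of 0.05. With 3 arrays per group, the smallest p an exact permutation test of 1 value allows is 0.1, so limma's test, which pools the spread across genes, was used. The number of arrays limits the precision. All samples come from 1 cell line, so p-values measure the spread between these cultures. Where no probe of a gene was well above background on any array of a group, the change is a bound, printed as "at least": the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

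Before the data were examined, 38 gene lists were fixed, including markers of other cell types. The 36 lists with at least 5 tested members were compared with all other features by camera in limma, with a preset correlation of 0.01 between genes. An estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives. The genes named in the text were set by a rule written before the data were examined. It names FN1, COL1A1, COL4A1, ACTA2, VIM, CDH1, CCN2, TGFB1 and TXNIP whatever their values. It adds the 12 largest rises and 12 largest falls among named genes that passed the test and whose groups did not overlap, and up to 4 members of each list with the smallest p. A few genes that the rule names are not reported here.

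Alternatives were quantile normalization, median centring, no scaling, normexp background correction (offset 50), the authors' value table, other filters on dim probes, flagged spots kept, other rules for several probes, the replicate number or the slide as a block, other variance models, a 2-fold threshold, and leaving out each array. The files hold no mean spot signal, so normexp used the median spot and background signals. Slide 1 held 4 arrays, the 3 normal glucose arrays and high glucose replicate 1, and the other 2 high glucose arrays lay on a slide each. On simulated data with the means and spreads of 18037 of these features and 3 arrays against 3, limma recovered 48% of 100 genes changed by 1 on the log2 scale and 2% of 100 genes changed by 0.5, with 4 false calls among 54. In the simulation few features changed and genes varied independently, unlike in these data. Its shares therefore do not give the recovery or the false calls of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.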

Results

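Expression in HK-2 cells, an immortalised line that retains features of the human proximal tubule, was measured after 72 h in 25 mM glucose (3 samples) and in 5.5 mM glucose (3 samples). The comparison asks which transcripts differ in high glucose, and the series title relates them to fibrosis of the renal tubule. Between 22256 and 23628 probes per array were well above background. Arrays of 1 group correlated at 0.987 to 0.995 across features and arrays of different groups at 0.968 to 0.986. The first principal component held 67.1% of the variance and separated the groups. Changes below are log2 differences, high minus normal glucose, with their standard errors from limma and n = 3 per group.

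In high glucose, replication-dependent histone genes, metallothionein genes, nuclear genes of the respiratory chain and ribosomal protein genes were lower as lists. All 4 calls were lost with an estimated correlation between genes (adjusted p = 0.70), and those of the respiratory chain and ribosomal protein genes also with quantile normalization. Genes of long span tended to be higher, and so did zinc finger genes, a family formed after the data were seen whose call was also lost with an estimated correlation (adjusted p = 0.49). TXNIP, the arrestin-family gene that is a classic target of the glucose sensor MondoA, rose 1.37-fold. SLC5A3, which encodes the myo-inositol transporter, and NFAT5, the transcription factor of the response to hypertonicity, rose 2.63-fold and 2.01-fold. FN1, COL1A1 and COL4A1, the fibronectin and collagen genes fixed by name in advance, did not pass the test. Some collagen genes of the matrix list did, among them COL8A1, which was higher, and COL16A1, which was lower. Neither stayed called without normal glucose replicate 1. COL16A1 also lost its call with quantile normalization (limma, adjusted p = 0.0545) and without scaling (0.094), and COL8A1 without the filter on dim probes.

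Among 18049 features tested, 7879 (43.7%) differed between the groups, 3519 higher and 4360 lower in high glucose. Without scaling between arrays the split was 4356 higher and 2399 lower, and with quantile normalization it was 3930 and 3486, so the balance of directions depends on the scaling. The median change of all features was -0.12 and moved to -0.01 without scaling, so shifts of gene lists are given relative to that median. Most changes were small: the median size among changed features was 0.62, 91.7% were under 2-fold, and 483 higher and 171 lower features reached 2-fold. The groups did not overlap in 58.1% of features, where chance gives 10%. Of the features that differed, 6521 had a RefSeq name.

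The count rests on few arrays. Without normal glucose replicate 1 it was 857, without high glucose replicate 1 it was 2907, and without high glucose replicate 3 it was 3902. In each of these fits all 7879 changed features kept their sign, but each fit reuses all but 1 of the arrays that gave the calls. A called feature could hardly change sign there, so this adds no independent support. Without normal glucose replicate 1, 7519 features had an unadjusted p under 0.05 in limma, against 9869 with all arrays. With slide as a block, which leaves high glucose replicate 1 against the 3 normal glucose arrays of its slide, no feature passed in limma and 4949 had an unadjusted p under 0.05. The difference of high glucose replicate 1 and 1 normal glucose array correlated with the difference of the other high and normal glucose arrays at 0.639 to 0.827 across 18037 features, by the array chosen. These differences share no array, and the features are not independent replicates.

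Of the genes fixed in advance as markers of fibrosis and of epithelial identity, VIM, an intermediate filament gene of mesenchymal cells, was the only one reported here to pass the test, and it was lower in high glucose (change -0.30, SE 0.10, adjusted p = 0.044). VIM no longer passed with quantile normalization (change -0.05, adjusted p = 0.71), without scaling (adjusted p = 0.18) or when any 1 array was left out (adjusted p from 0.066 to 0.12). FN1, which encodes fibronectin, had a change of -0.07 (SE 0.13, adjusted p = 0.65), and COL1A1 one of -0.08 (SE 0.10, adjusted p = 0.51). COL4A1, a basement membrane collagen gene, had a change of -0.32 (SE 0.21, adjusted p = 0.23). CCN2, the connective tissue growth factor gene, had a change of -0.45 (SE 0.23, adjusted p = 0.15). The values for TGFB1 (-0.20, SE 0.22) and CDH1 (-0.19, SE 0.10) did not pass either, with adjusted p of 0.47 and 0.13. COL4A1 and CCN2 were called lower when normal glucose replicate 3 was left out (changes -0.54 and -0.68, adjusted p = 0.023 and 0.017). With a replicate block CCN2 was called lower (adjusted p = 0.032) and VIM lost its call (0.058). ACTA2, the smooth muscle actin gene, was not tested, because it was well above background on 2 normal and 1 high glucose arrays. TXNIP rose by 0.45 (SE 0.10, adjusted p = 0.017) and was higher on each high glucose array than on any normal glucose array. Its call was lost without normal glucose replicate 1 (adjusted p = 0.073), high glucose replicate 1 (0.065) or high glucose replicate 3 (0.053).

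**Figure D1:**
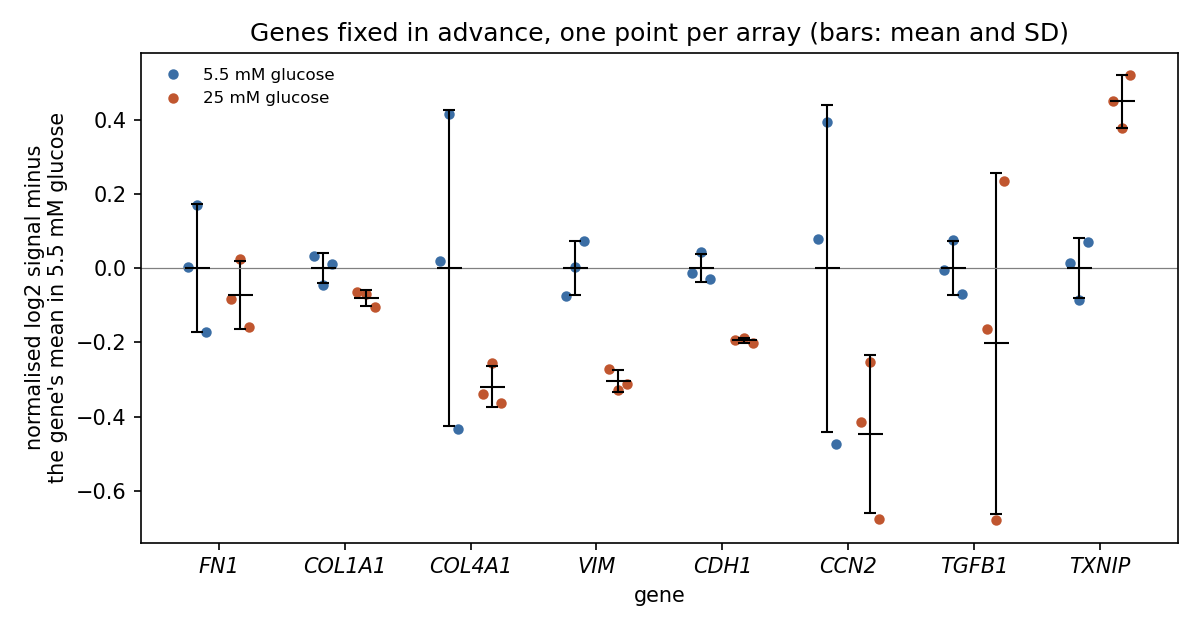
Normalised log2 signal of 8 genes fixed in advance, minus each gene's mean in 5.5 mM glucose, with 1 point per array (3 per group) and bars for the group mean and SD. The TXNIP points in 25 mM glucose lie above those in 5.5 mM glucose, with a mean difference of 0.45, while COL4A1 and CCN2 spread widely among the arrays in 5.5 mM glucose.

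The numbers of list members that rose and fell depend on the scaling and on single arrays. Of 33 lists with more members changed one way, the balance turned in 6 with quantile normalization and in 9 without scaling. Of 130 called list members with the smallest p, up to 4 per list, 33 stayed called without normal glucose replicate 1 and 83 without high glucose replicate 1.

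The matrix and fibrosis list did not stand apart from other features. Of its 43 tested members, 1 rose, 9 fell and 33 did not pass (adjusted over the list alone, 0 rose and 2 fell), against 8 that rose and 3 that fell with quantile normalization and 4 and 2 without scaling. Its median lay -0.04 from that of all features (camera, adjusted p = 0.60). Genes that fell included LOX, a collagen cross-linking enzyme gene (change -0.51, SE 0.10), and MMP9, a matrix metalloproteinase gene (change -0.53, SE 0.11), and COL8A1, named after its value was seen as the member that rose, had a change of 0.40 (SE 0.13). Of 34 genes of TGF-beta signalling, 9 rose and 1 fell (adjusted over the list alone, 6 and 1), with no shift of the list past the threshold (adjusted p = 0.52). SKIL, a feedback inhibitor of SMAD proteins, rose by 0.85 (SE 0.15), ITGAV by 0.94 (SE 0.23) and BMP2 by 0.58 (SE 0.11), and ID1 fell by 0.83 (SE 0.11). Among 26 epithelial genes, 3 rose and 10 fell (the same numbers adjusted over the list alone), with KRT18 at -0.90 (SE 0.16) and SPINT2 at -0.81 (SE 0.14). Among 24 mesenchymal genes, 3 rose and 4 fell (adjusted over the list alone, 1 and 1), against 6 and 3 with quantile normalization and 4 and 1 without scaling. The repressors of epithelial genes ZEB2 (0.88, SE 0.14) and ZEB1 (1.04, SE 0.30) were higher, and CNN1 (-0.53, SE 0.12) was lower, the call of ZEB1 being lost in 4 of 6 leave-one-out fits. These 2 lists gave adjusted p of 0.57 and 0.97.

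Genes tied to glucose handling and osmolality went both ways. Of 24 glycolysis genes, 2 rose and 9 fell, and the same held adjusted over the list alone (camera, adjusted p = 0.52), but 4 rose and 2 fell with quantile normalization. TPI1 was lower (change -0.76, SE 0.11) and SLC16A1, a monocarboxylate transporter gene, was higher (change 1.14, SE 0.20). Among 16 glucose-responsive targets of MondoA and ChREBP, 2 rose and 2 fell (adjusted over the list alone, 1 and 2, adjusted p = 0.74). ARRDC4, a relative of TXNIP, rose by 0.87 (SE 0.27) and TKFC fell by 0.78 (SE 0.10). The call of ARRDC4 was lost in 5 of 6 leave-one-out fits. Of 17 genes of the polyol, hexosamine and glycation routes, 4 rose and 3 fell (adjusted over the list alone, 6 and 4, adjusted p = 0.60). OGT, the enzyme gene that adds O-GlcNAc to proteins, rose by 1.22 (SE 0.19) and PGM3 by 0.83 (SE 0.18), and AKR1A1 fell by 1.02 (SE 0.24). Of 12 osmotic response genes, 4 rose and none fell, with the same result adjusted over the list alone. These were SLC5A3 (1.40, SE 0.23), SLC38A2 (0.74, SE 0.13), NFAT5 (1.01, SE 0.21) and the chaperone gene HSPH1 (1.03, SE 0.28), while the list as a whole did not pass (adjusted p = 0.60). Without normal glucose replicate 1 only SLC5A3 stayed called.

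Of the 36 lists, 4 passed camera, all lower in high glucose, and all 4 missed the threshold with an estimated correlation between genes (adjusted p = 0.70). Replication-dependent histone genes, which encode the core and linker histones made during DNA synthesis, fell in 39 of 48 tested members and rose in none (adjusted over the list alone, 40 fell). The estimated correlation between these genes was 0.504, so the members are not independent measurements. Their median lay -0.38 from that of all features (adjusted p = 1.75e-06), with H1-3 at -0.89 (SE 0.16) and H2AC16 at -0.85 (SE 0.15). Without normal glucose replicate 1 the number called lower was 1 for the histones, 5 for the ribosomal proteins and 3 for the respiratory chain genes. Without high glucose replicate 1 it was 12, 15 and 8. H1-3 and H2AC16 missed the threshold narrowly without normal glucose replicate 1 (limma, adjusted p = 0.0505 and 0.0501). Of 77 ribosomal protein genes, 1 rose and 37 fell (adjusted over the list alone, 2 and 37), with a relative median of -0.21 (adjusted p = 1.02e-05). RPS16 was at -0.87 (SE 0.12), RPS9 at -0.78 (SE 0.12) and RPL27A, the member that rose, at 0.78 (SE 0.11), which shrank to 0.292 with normexp. Of 10 metallothionein genes, which encode small metal-binding proteins, 8 fell and none rose (the same adjusted over the list alone), with a relative median of -0.60 (adjusted p = 0.00052). MT1G was at -0.93 (SE 0.11) and MT1X at -0.73 (SE 0.10), and probes of this family can bind transcripts of close relatives. Of 45 nuclear genes of the respiratory chain, 2 rose and 27 fell (adjusted over the list alone, 2 and 28), with a relative median of -0.33 (adjusted p = 0.00052). CYC1 was at -0.82 (SE 0.12), NDUFS7 at -0.77 (SE 0.12) and COX5B at -0.77 (SE 0.13).

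With quantile normalization the ribosomal proteins (relative median -0.0002, adjusted p = 0.86) and the respiratory chain genes (-0.13, adjusted p = 0.35) no longer passed, with 9 and 11 members that fell, while histones (-0.37) and metallothioneins (-0.36) did. Members of these lists are short: the median gene span was 487 bp for the histones, 1334 bp for the metallothioneins, 5011 bp for the ribosomal proteins and 10640 bp for the respiratory chain genes. Other lists of short genes shifted less, some of them only slightly less than the ribosomal proteins. Oxidant enzymes (9239 bp) had a relative median of -0.18 and leukocyte markers (3951 bp) one of -0.15. Immediate early genes (5798 bp) lay at -0.04 and NF-kB and inflammation genes (6082 bp) at -0.03.

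**Figure D2:**
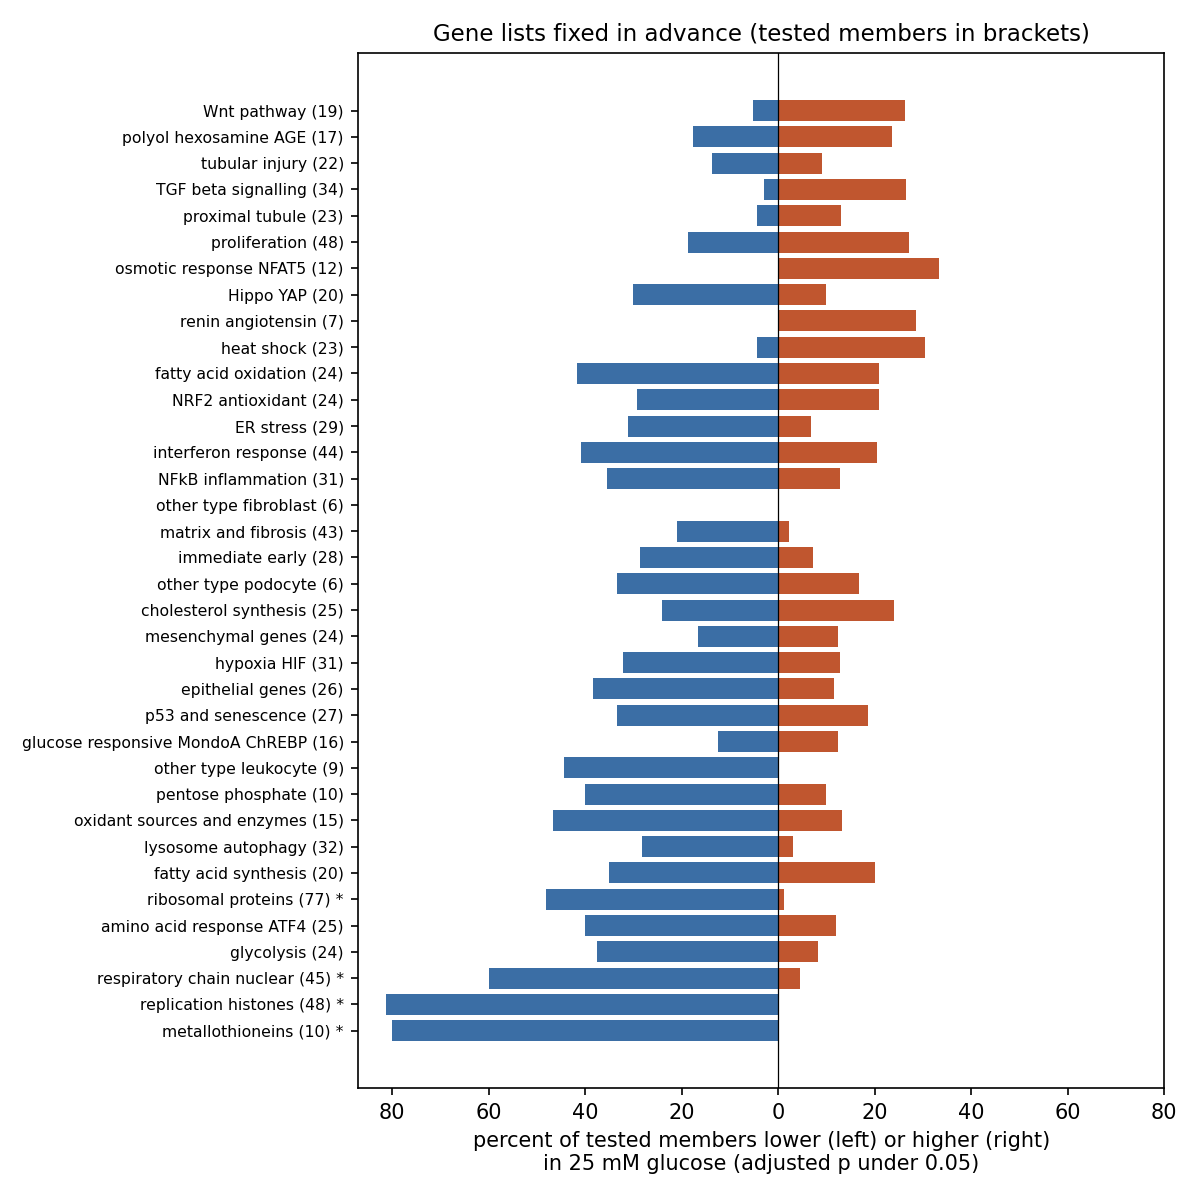
Percent of tested members of each gene list that were lower (left, blue) or higher (right, orange) in 25 mM glucose at an adjusted p under 0.05, with the number of tested members in brackets, lists ordered by relative median change and an asterisk for lists past camera's threshold. Histones (39 of 48 lower) and metallothioneins (8 of 10 lower) have bars on the left side alone.

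Across 13608 protein-coding genes, the change rose with gene span (Spearman rho 0.42 across genes, which are not independent replicates). The median change was -0.42 for 1606 genes under 5 kb and 0.28 for 1450 genes of 100 to 200 kb. On slide 1 alone the corresponding medians were -0.43 and 0.27. On single arrays, rho between a gene's deviation from its mean and its span was -0.39, -0.32 and -0.29 for the normal glucose arrays and 0.39, 0.38 and 0.34 for the high glucose arrays. With this trend removed from each array, an alternative added after the data were seen, 4808 of 14381 named features differed (2657 higher and 2151 lower), 3853 of the 6521 named calls were kept, and no list passed camera (lowest adjusted p = 0.18).

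**Figure D3:**
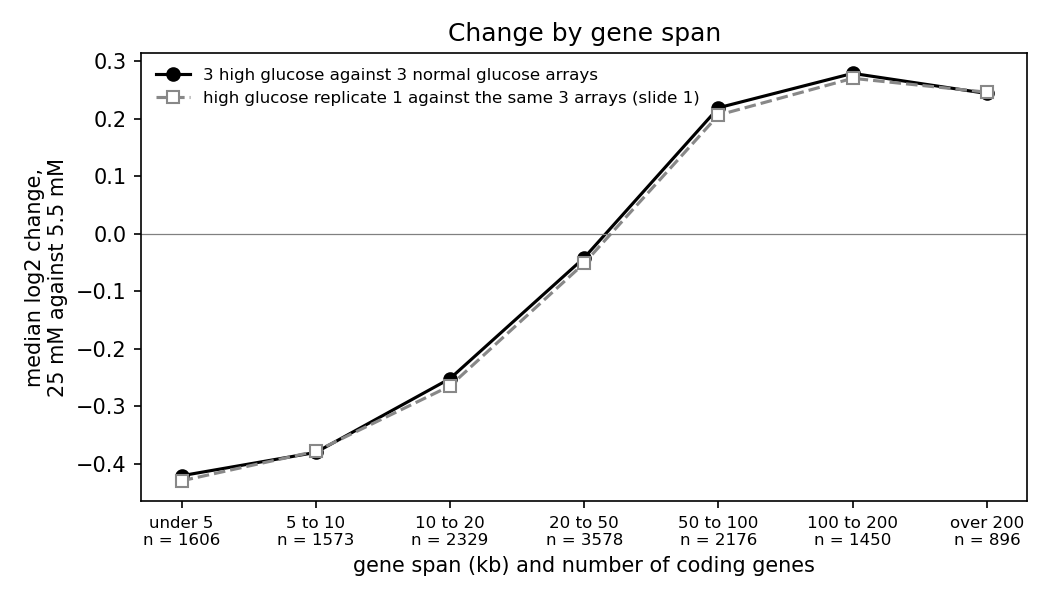
Median log2 change, 25 mM against 5.5 mM glucose, of protein-coding genes in bins of gene span in kb, with the number of genes under each bin, from all arrays (filled circles) and from the 4 arrays of slide 1 (open squares). The medians go from -0.42 in the shortest bin to 0.28 in the bin of 100 to 200 kb on all arrays.

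The largest changes among named genes lay near the detection limit, and 19 of the 24 genes named by rank were not well above background on all 6 arrays. OPCML, a cell adhesion gene of the immunoglobulin family, was at least 3.05-fold higher in high glucose (adjusted p = 0.0039). EID3, TRMT9B, TECRL and CARF were at least 2.99-fold, 2.06-fold, 1.81-fold and 1.65-fold higher. These bounds are estimates: with 1 array left out they fell as low as 2.72-fold, 1.5-fold, 1.58-fold and 1.45-fold, and that of OPCML to 2.62-fold. For the pseudogene ANKRD20A8P the bound of 2.41-fold fell to 1.53-fold without high glucose replicate 2, and for RYR3 that of 1.22-fold fell to 0.986-fold without high glucose replicate 1, which is no rise. SND1-IT1 had a change of 1.90 (SE 0.25), with dim signals in normal glucose, and its other tested probe gave 1.24. WDR17 was called higher by a probe that was well above background on no normal glucose array, so no size is given, and without the filter on dim probes another probe stood for the gene (change 0.30, adjusted p = 0.67). TMEM65, which encodes a mitochondrial membrane protein, rose 3.58-fold and was bright on all arrays. The noncoding transcripts HYMAI, from an imprinted locus, and ASAP1-IT1, named as an intronic transcript, rose 3.95-fold and 3.55-fold. On the other side, LTF, the lactoferrin gene, was at least 3.32-fold lower (adjusted p = 0.0092). EPHA8, PGLYRP3, PIEZO2 and PLPPR5-AS1 were at least 2.26-fold, 2.14-fold, 1.69-fold and 1.66-fold lower. With 1 array left out these bounds fell as low as 2.04-fold, 1.95-fold, 1.42-fold and 1.42-fold, and that of LTF to 2.88-fold. BDNF-AS, PLXNA4, NR0B2 and SEC16B were dim on some high glucose arrays, with changes of -1.53, -1.48, -1.43 and -1.29. Another probe of PLXNA4, well above background on all arrays, gave -0.33 (adjusted p = 0.40). HPYR1 was called lower, but its change with slide as a block was -0.196, and its call was lost with quantile normalization, without scaling and with normexp. The keratin pseudogene KRT18P55 (-1.29, SE 0.35) and OR4D10 (-1.71, SE 0.59) were well above background on all arrays. OR4D10 had an adjusted p of 0.04965, its change was -1.04 without normal glucose replicate 3, and its call was lost there, with quantile normalization, without scaling and with normexp. Because the rule took genes whose groups did not overlap, leaving out 1 array could not change their sign. Of these 24 genes, 11 stayed past the threshold in all 6 leave-one-out fits, among them OPCML, EID3, HYMAI, TMEM65, ASAP1-IT1 and LTF. Without normal glucose replicate 1, 12 of the 24 passed.

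Of the markers of other cell types, 6 of fibroblasts were tested and none passed, of 9 leukocyte markers 4 fell and none rose, and of 6 podocyte markers 1 rose and 2 fell (the same numbers adjusted over the list alone). Of 3 endothelial markers 1 fell (adjusted over the list alone, 2), and of 4 markers of the distal nephron none passed.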

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

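The normexp settings, the restriction to named features, the removal of the gene-span trend, and the slide block and further scalings for gene lists were chosen after the data were seen. Against 7879 changed features (3519 higher, 4360 lower), dropping the filter on dim probes gave 3312 (1432 and 1880), no pooling of the variance 4274 (1699 and 2575), an adjusted p with 2-fold 654 (483 and 171) and an unadjusted p with 2-fold 677 (490 and 187). Array weights gave 15369 (6534 and 8835), a fit in which normal glucose replicate 1 had a weight of 630 and no other array more than 2.33. Without scaling the lower features numbered 2399. Removal of the span trend gave 4808, of which 2151 were lower, from 14381 features. The slide as a block gave 0 (0 higher and 0 lower; 4949 at an unadjusted p under 0.05), a fit that uses 4 arrays for the contrast. Leaving out 1 array gave 857 to 9370 changed features, 392 to 4309 higher and 465 to 5061 lower; the low counts came without normal glucose replicate 1 (857), high glucose replicate 1 (2907) and high glucose replicate 3 (3902). The fit with a replicate block gave 9055 (4033 and 5022) and 4 lists. Same-numbered samples deviated from their group means with correlations across genes of -0.01, 0.31 and 0.35. Normal glucose replicates 2 and 3 correlated best with their own number and replicate 1 did not, so a pairing by number stays possible. The fit without the block was set as the main one because the series' design text states no model. The other settings stayed within 1.5 times of the counts, and of the 7879 features 6837 were kept in the same direction with quantile normalization, 5917 without scaling and 6908 with normexp.

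Of the 4 lists past the threshold, quantile normalization kept 2, normexp with quantile normalization 2, an estimated correlation 0 and removal of the span trend 0, while fry, which makes no comparison with other genes, called 23. Leaving out any 1 array kept 4. The matrix and fibrosis list had a relative median of -0.041, against 0.024 with quantile normalization and 0.012 without the filter on dim probes. The cause of this change of sign was not tested. The adjusted p of the list ran from 0.0060 to 0.97 over the alternatives. The value of 0.0060 came from fry, which called the list lower. It tests the changes themselves, with a list median of -0.166, where all features had a median of -0.124. Genes that had not passed and changed sign were FN1 (0.037 without scaling, -0.16 to 0.012 when 1 array was left out), COL1A1 (0.031 without scaling, 0.051 after removal of the span trend) and TGFB1 (-0.42 to 0.036 when 1 array was left out); the cause was not tested. Of 750 values of the 32 named genes under the alternatives, 599 kept direction and side of the threshold, 137 lost their call and 9 gained one; of 684 values of gene lists, 605 kept both, 11 lost their call, 19 gained one and 49 changed sign. Of 130 called list members with the smallest p, up to 4 per list, none changed sign with quantile normalization or normexp, but 23 and 14 of them shrank by over 1.5 times. Of those named, these were SPINT2, TPI1, MT1X, FTL, GPX1, PGLS, COX5B, RPS16, RPS9 and ID1 with quantile normalization, and ACADS, ETFDH, ZEB2, MT1G, REL, LCN2, ENPEP and RPL27A with normexp. Signals near background limit the genes named by rank: all 24 kept their sign with normexp, 15 kept their call, and the median size of their change went from 1.83 to 0.366, since the offset shrinks dim signals. Without the filter on dim probes 11 of the 24 kept their call, with normexp and quantile normalization 13, and with no pooling of the variance 10. With quantile normalization alone 22 did, and without scaling 22. A block for scan date was not run, since the arrays share 1 date, and the authors' value table changed nothing, since it holds the same values.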

Other observations

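The tests of the slide, of bright signals, of the normal glucose replicates and of the zinc finger families were chosen after the result was seen. Immune and stress genes split within their lists, none of which passed camera (lowest adjusted p among the lists of these 2 paragraphs 0.24). Without scaling, more members rose than fell in the lists of ER stress, ATF4, NRF2, tubular injury, fatty acid synthesis, hypoxia (7 and 5) and Hippo (5 and 1) genes, and with the span trend removed more rose than fell in the NF-kB (9 and 4), oxidant enzyme (3 and 1) and immediate early (4 and 3) lists, so the balance of directions given below for these lists is not stable. Of 44 interferon response genes, 9 rose and 18 fell (the same adjusted over the list alone, but 10 and 10 with the span trend removed), with IFITM1, IFITM2 and IFITM3, small antiviral membrane proteins, at -0.92, -0.91 and -0.87 and PARP14 at 0.82. Of 31 NF-kB and inflammation genes, 4 rose and 11 fell (the same adjusted over the list alone), with REL at 0.78, BIRC3 at 1.41 and LCN2, a marker of tubular injury, at -0.84 (-0.355 with normexp). Of 22 tubular injury genes, 2 rose and 3 fell (adjusted over the list alone, 2 and 1), with HAVCR1, which encodes KIM-1, at 0.54. Of 24 NRF2 targets, 5 rose and 7 fell (the same adjusted over the list alone): GCLC (1.37) and SLC7A11 (1.07), of glutathione synthesis and cystine uptake, were higher, and FTL (-0.69, or -0.384 with quantile normalization) and HMOX1 (-0.52), of iron storage and haem breakdown, were lower. Of 15 oxidant enzymes, 2 rose and 7 fell (the same adjusted over the list alone), with PRDX5 at -0.83 and GPX1 at -0.67 (-0.373 with quantile normalization). Heat shock genes rose in 7 of 23 and fell in 1 (adjusted over the list alone, 3 and 1), with HSPA4L at 0.71. Of 29 ER stress genes, 2 rose and 9 fell (adjusted over the list alone, 1 and 8), with ATF6 at 0.68 and SDF2L1 at -0.89, and of 25 genes of the ATF4 response 3 rose and 10 fell (adjusted over the list alone, 5 and 10), with MTHFD2 at 0.71 and PHGDH at -0.83. Of 28 immediate early genes, 2 rose and 8 fell (adjusted over the list alone, 2 and 7), with EGR1 at -0.59, and of 27 p53 and senescence genes 5 rose and 9 fell (adjusted over the list alone, 6 and 11), with FDXR at -0.62.

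Cholesterol synthesis genes rose in 6 and fell in 6 of 25 (adjusted over the list alone, 6 and 7): HMGCS1 (0.74), STARD4 (0.90) and INSIG1 (0.65) were higher and PMVK (-0.70) was lower. Fatty acid synthesis genes rose in 4 and fell in 7 of 20, and fatty acid oxidation genes rose in 5 and fell in 10 of 24 (both the same adjusted over the list alone), with ACSS2 at -0.66, ACADS at -0.88 and ETFDH at 0.77. In the pentose phosphate list 1 of 10 rose and 4 fell (the same adjusted over the list alone), with PGLS at -0.65. Of 48 proliferation genes 13 rose and 9 fell (the same adjusted over the list alone, but 19 and 5 with quantile normalization), with BUB1B (0.67) and CENPE (0.88) of the mitotic checkpoint higher. Of 31 hypoxia genes 4 rose and 10 fell (the same adjusted over the list alone), with KDM3A at 0.56. Of 32 lysosome genes 1 rose and 9 fell (adjusted over the list alone, 0 and 6), with HEXA at -0.97. Of 19 Wnt pathway genes 5 rose and 1 fell (adjusted over the list alone, 2 and 0), with CTNNB1 at 0.64, and of 20 Hippo pathway genes 2 rose and 6 fell (adjusted over the list alone, 3 and 6), with TEAD1 at 0.76 and WWTR1 at -0.69. Of 23 proximal tubule genes 3 rose and 1 fell (adjusted over the list alone, 1 and 1), with GATM at 0.59 and MIOX at -0.69, and in the renin-angiotensin list 2 of 7 rose and none fell (the same adjusted over the list alone), with ENPEP at 1.01, which did not pass with normexp.

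The 4 lists, of genes with short span and mostly abundant transcripts, were lower on each high glucose array. A slide difference is argued against: on high glucose replicate 1, which shares its slide with the normal glucose arrays, their mean shift was -0.353, against -0.391 for the arrays on other slides. Compression of bright signals as the whole cause is argued against for histones and metallothioneins, whose medians lay -0.455 (bootstrap SE 0.0465) and -0.391 (0.0373) from coding genes of like brightness. The bootstrap resampled list members as if independent, so its SE does not measure the spread between cultures. On high glucose replicates 1 to 3 the values were -0.453, -0.351 and -0.578 for histones. For metallothioneins they were -0.42, -0.323 and -0.401. Compression stays open for the respiratory chain genes (-0.152, 0.0515) and the ribosomal proteins (-0.075, 0.0231), which lay closer to coding genes of like brightness and whose calls ended with quantile normalization. A yield that depends on transcript length or RNA integrity also stays open. Outside the lists the change rose with gene span (rho 0.415 across 13430 genes). Gene span counts introns and transcript length was not measured, so this value cannot decide on such a yield. The normal glucose arrays differed among themselves by 0.106 along the list shift, against a group difference of 0.376. Once the span trend was removed, the relative medians went from -0.378 to -0.0927 for histones, -0.598 to -0.318 for metallothioneins, -0.328 to -0.138 for respiratory chain genes and -0.206 to 0.0391 for ribosomal proteins (SD of members 0.22 to 0.339), so the calls ended with smaller shifts, and an effect of glucose on these genes, untested, may share the trend.

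Families of gene symbols, formed after the data were seen, shifted together in 12 of 54 cases by camera, and in 0 with an estimated correlation (adjusted p = 0.49 for each of the 12). Zinc finger (ZNF) genes, most of them transcription factors, rose in 208 and fell in 43 of 418 (relative median 0.519, adjusted p = 7.19e-09), and CEP genes of the centrosome rose in 23 and fell in 1 of 36 (0.692, adjusted p = 7.47e-07). Median centring and no scaling move each array by a constant, so they could hardly change these relative medians. With quantile normalization the relative medians of ZNF and CEP genes were 0.471 and 0.636, and with normexp they shrank to 0.273 and 0.422. The other 10 families no longer passed once the span trend was removed (camera, lowest adjusted p = 0.122). That loss does not show that the trend accounts for each of them, since TAF genes went from a relative median of 0.392 to 0.341 and NUP genes from 0.58 to 0.395 (SD of members 0.393 and 0.527 after removal). In other families the shift itself shrank or turned: RPL (-0.198 to 0.0391), RPS (-0.186 to 0.0299), KRTAP (-0.209 to 0.0744), KRT (-0.219 to -0.0837) and USP (0.435 to 0.168). MRPL (-0.355 to -0.162), COX (-0.394 to -0.247) and KIF (0.521 to 0.275) kept a part of theirs. The COL family of 26 collagen genes, which had not passed before (3 rose and 5 fell, adjusted p = 0.34), passed as lower once the span trend was removed (adjusted p = 0.0285). The span trend as the whole cause is argued against for the ZNF and CEP families, which kept relative medians of 0.467 and 0.49 after its removal. The larger adjusted p was 0.000454 in camera with the preset correlation, and an estimated correlation was not run after removal. For ZNF genes the removal could take away little. Their median span was 23150 bp, and coding genes of 20 to 50 kb had a median change of -0.04. A larger share of nuclear or unspliced RNA in high glucose stays open: 4 intronic transcripts not named by rank lay 0.935 above all features. The 3 nuclear RNAs fixed for the test went both ways, with a relative median of -0.126. Of these, MALAT1 rose by 1.26, PVT1 had a change of -0.33 and MEG3 one of -0.25. Both sets are too small to decide.

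Normal glucose replicates 2 and 3 differed along the same axis as the groups. Across 14370 named genes, replicate 3 minus replicate 2 correlated at 0.527 with the high glucose mean minus replicate 1, a pair of differences that share no array. The corresponding correlation was 0.566 for replicate 3 minus replicate 1 and 0.115 for replicate 1 minus replicate 2. The span trend is argued against as the cause, since the correlation was 0.522 once it was removed. A wrong group label on replicate 3 is argued against, since it correlated better with its own group (0.990) than with the other (0.986), by 0.00452. A difference between the cultures or batches stays open, and no biological explanation was tested.

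The real grouping gave 7879 changed features and the highest of the other splits gave 0. The 6 arrays allow 10 splits, of which 1 gave as many, too few for a share under 0.05.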
